A study of Mus musculus with 2 samples.

How the data were processed

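The libraries were made from total RNA of mouse splenic CD4+CD25+ cells after co-culture with SVEC4-10 endothelial cells, per the labels' protocols, with 1 library from the control and 1 from the Capns1 knockdown co-culture. Groups were taken from the treatment label of each sample. The columns of the deposited table were matched to the samples by the meaning of their prefixes, Cont for the control and Si for the interfering RNA, which the sample titles do not use, and the direction of every fold rests on this match. Trimmomatic 0.39 and BWA 0.7.17 and the genome builds mm8 and GRCm39 are named in the submitters' processing notes, without their roles. How reads were assigned to genes, and whether strand was used, is not given in the sources used here, so reads of paralogs, overlapping genes and antisense pairs cannot be told apart. BWA is not a splice-aware aligner, so reads that cross exon junctions can be clipped or lost. Because 2 builds are named, no coordinates are printed.

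The authors deposited 1 table for both libraries. The counts, per the file headers, are mapped reads per gene, not normalized. The authors also deposited counts scaled by 1 factor per library to equal totals and counts scaled by a factor named TMM. These are of the unit signal and were used only to learn how the authors scaled the values. An unnamed column of the deposited table holds log2 ratios, and tested on the file it equals the log2 ratio of the authors' total-scaled columns to within 0.005. In the authors' deposited table these log2 ratios run from -1.58 to 1.16, with 22 genes at or below -1 and 1 gene at or above 1. The authors' TMM scaling moved the log2 ratio of a gene by 0.018.

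The row holding each library's total was left out of library sizes and tests. The listed genes held 47724379 reads in the control and 46938963 in the knockdown co-culture library, and the rest of the deposited totals, 0.782% and 0.764%, belongs to no listed gene. Each of the 14774 listed genes has at least 100 reads in the control library, and the lowest value in the knockdown co-culture library is 37 reads. A minimum in the control alone keeps genes that are lower in the other library and leaves out genes that are higher from a low start. The 10 most abundant genes took 2.92% and 3.11% of the reads.

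Library sizes were computed with edgeR 4.0.16 (TMM factors 1.004 and 0.996) under R 4.3.3, and all further steps were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. With 1 library per group a dispersion cannot be estimated, so no quasi-likelihood test was fitted. A gene was called higher or lower when its fold in CPM, knockdown over control co-culture, was at least 2 or at most 0.5 and the exact 95% Clopper-Pearson interval of the ratio of reads excluded 1. Genes entered with at least 1 CPM in a library and at least 10 reads in both together, which all listed genes met. A count of 0 would have been set to a floor of 3 reads, and no listed gene needed it. Log2 folds used a prior count of 0.5.

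For each gene list, the median log2 fold of the measured members was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean expression. A list stands apart when it lies in the lowest or highest 2.5%, as a description of these libraries. Of 42 lists, 39 had at least 5 measured members, 31 of them gene lists and 8 cell type marker lists. The genes named were fixed by a rule before the data were examined. It takes the 12 called genes per direction with the fold farthest from 1 at its nearer interval bound, leaving out predicted genes, pseudogenes and receptor segments. It adds a fixed set of Treg, cytokine, calpain, T cell and endothelial genes whatever their values. From each list standing apart, or with at least 3 called members, it takes up to 4 called members, or the 2 most abundant if none is called. Further genes are named where stated, chosen after their values were seen. 1 gene that the rule takes is not reported here. Transcript lengths and GC content came from the longest GENCODE M21 transcript of each gene. Genes were matched by NCBI Gene ID, or else by symbol, which gave values for 13381 genes (90.6%).

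The calls and lists were tested on simulated data for this comparison, with counts drawn for the 14774 genes and 200 of them changed. Of 50 genes changed 2-fold 60% were called, of 50 changed 3-fold and 50 changed 4-fold 100%, and of 50 changed 1.5-fold 0%. Because a call needs an observed fold of at least 2, the shares at 2-fold and 1.5-fold follow largely from that threshold. Of 14574 unchanged genes 0 were called, and their intervals covered the true ratio in 95.2% of cases. Of 200 unchanged lists 7 stood apart, and of 20 lists shifted by 0.15 on the log2 scale 20 did. The simulation holds counting error only.

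Alternatives listed before the data were examined were DESeq2 1.42.0 size factors, total counts, upper-quartile scaling, other filters, fold thresholds and prior counts, an interval wholly beyond 2-fold, an assumed biological coefficient of variation of 0.2, thinning of the deeper library, leaving out ribosomal genes, 10 expression bins and the mean in place of the median. Alternatives added after the data were seen were a minimum of 400 reads in both libraries together, the deposited totals as library sizes, removal of the trend on length and GC content, and random lists matched on length. A further 5 lists were added after the data were seen, for tissue macrophages, neutrophil granules and precursors, mast cells with basophils and eosinophils, chemokines, and matrix metalloproteinases, and are used only in the closing section.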

Results

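RNA was sequenced from mouse cells labelled as regulatory T cells (Tregs), the CD4 T cells that restrain immune responses under the transcription factor Foxp3. Because Foxp3 was low and markers of other cells were abundant in both libraries, as given below, Treg names only the label here. Per the labels, CD4+CD25+ cells were taken from C57BL/6 spleens and kept for 5 days with SVEC4-10 cells, a mouse endothelial line transformed with SV40. The endothelial cells had received either a control oligonucleotide or small interfering RNA against Capns1, which encodes the small regulatory subunit of the conventional calpains, a family of calcium-dependent proteases. Each condition had 1 library, named here the control co-culture library and the knockdown co-culture library. The deposited totals were 48100576 reads for the control and 47300284 reads for the knockdown co-culture, and 14774 genes were listed with counts in both. At this depth 3 reads corresponded to a library-scaled read count (CPM) of 0.0626 in the control and 0.0642 in the knockdown co-culture library. With 1 library per group no difference has a replicate check and no p-value is given. The 95% intervals below are exact intervals for the ratio of a gene's reads in these libraries. They compare the libraries, not the conditions, and cover counting error only, taking reads as independent. PCR reads without molecular identifiers are not independent molecules, so the intervals may be too narrow.

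Capns1 itself (NCBI Gene 12336) had 11650 reads in the control and 11015 in the knockdown co-culture library, or 243 and 236 CPM, a fold of 0.969 (95% interval 0.944 to 0.994). The interfering RNA was given to the endothelial cells, and how much of the sequenced RNA came from them was not measured, so this level does not check the labels. Of the calpain genes, Capn1, the catalytic subunit of calpain 1, stood at a fold of 1.03 (0.992 to 1.08) and Capn2, that of calpain 2, at 1.11 (1.08 to 1.14). Cast, which encodes the calpain inhibitor calpastatin, stood at 0.947 (0.917 to 0.978). The calpain list had 8 of its 10 members measured, with a median log2 fold of -0.07, and none of them was 2-fold apart.

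The comparison of the libraries asks how the RNA of the co-cultured cells differed when the endothelial partner had been given interfering RNA against Capns1. Genes of macrophages were lower in the knockdown co-culture library. The list of macrophage, monocyte and neutrophil markers, fixed before the data were examined, had a median log2 fold of -0.44, the lowest of all fixed lists, and 3 of its 19 measured members were at least 2-fold lower. C1qc and C1qb, which encode chains of complement C1q, stood at folds of 0.338 (95% interval 0.251 to 0.451; 194 and 64 reads) and 0.381 (0.301 to 0.480; 274 and 102 reads). Mrc1, the mannose receptor, stood at 0.403 (0.346 to 0.468), Siglec1, the sialoadhesin of tissue macrophages, at 0.421 (0.382 to 0.464), and the scavenger receptors Stab1 and Msr1 at 0.444 (0.391 to 0.502) and 0.488 (0.463 to 0.516). The only gene at least 2-fold higher was Lipg (NCBI Gene 16891), which encodes endothelial lipase, with 190 reads in the control and 417 in the knockdown co-culture library, a fold of 2.25 (1.89 to 2.68).

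In all, 1 gene was higher and 20 were lower by the rule fixed before the data were examined, a fold of at least 2 with an interval excluding 1. Of the 20, 17 had named symbols and 3 were predicted genes. Beyond those above, the rule for named genes took Cd5l, a soluble protein secreted by tissue macrophages, at 0.356 (0.242 to 0.515), F13a1, the coagulation factor XIII A chain, at 0.358 (0.306 to 0.417), Pf4, platelet factor 4, at 0.417 (0.373 to 0.466), and Arg1, arginase 1, at 0.446 (0.411 to 0.484). Adam8, a metalloprotease of myeloid cells, stood at 0.476 (0.445 to 0.508) and Rab3il1 at 0.487 (0.387 to 0.610). The most abundant of the 20 were Msr1 with 4097 and 1953 reads, Adam8 with 2825 and 1312 reads, and Arg1 with 1949 and 849 reads. The other 5 with named symbols, named after their values were seen, were Spef2, P2ry6, Olfm1, Cd244a and Cdh1, at folds from 0.431 to 0.489 and at 157 control reads or fewer. Every listed gene had at least 100 reads in the control library, while 402 had fewer in the knockdown co-culture library, so genes that were higher from a low control level are not among those analysed and the counts of higher and lower genes are not on equal terms. Among genes with at least 400 reads in both libraries together, 9 were lower and 1 was higher.

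**Figure D1:**
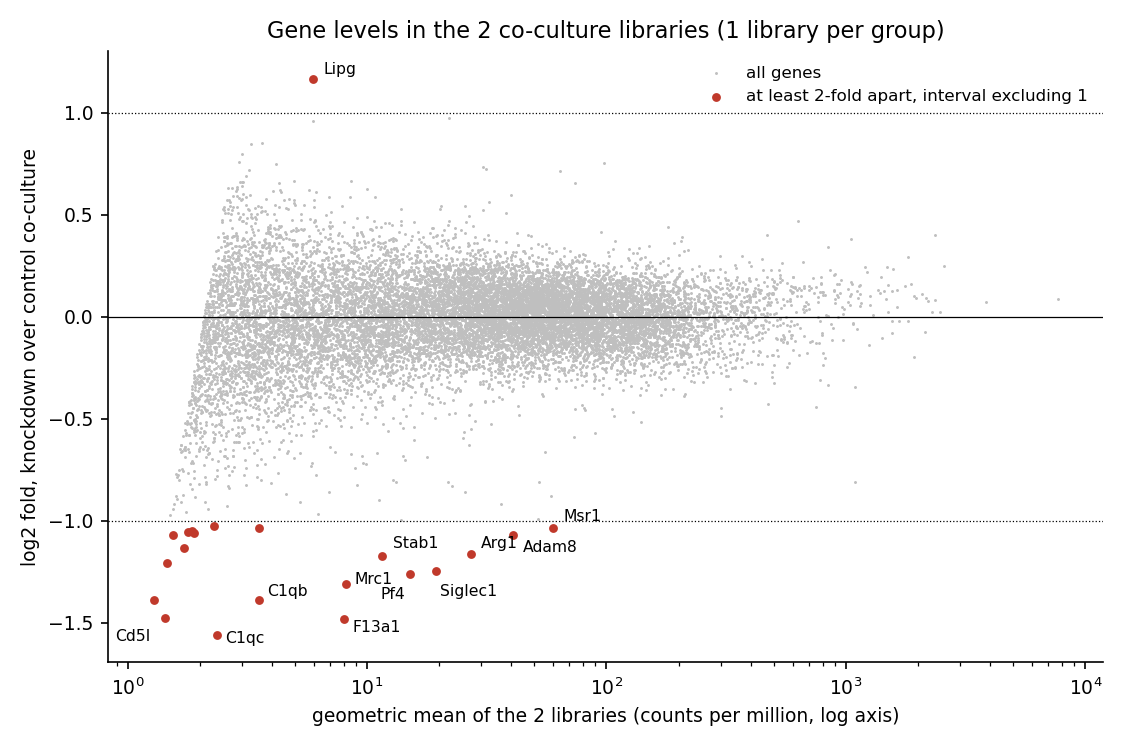
Each point is 1 of 14774 genes, placed by the geometric mean of its CPM in both libraries (log axis) and its log2 fold, knockdown over control co-culture (1 library per group). Red points are the 1 higher and 20 lower genes, dotted lines mark 2-fold, and the slanted left edge is the minimum of 100 control reads.

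Most genes lay close to equality. The log2 fold had a median of 0.00 and an SD of 0.20 over genes, and 98.5% of genes lay within 1.5-fold. At this depth small gaps exceed the counting error of independent reads. The intervals of 3581 genes lay above 1 and those of 3349 below, which is 46.9% of the genes. The spread between replicate cultures, against which such gaps would have to be set, is unknown here.

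Foxp3, Il2ra and Ctla4 were low in both libraries, and their intervals included 1. Foxp3 had 250 and 221 reads, or 5.22 and 4.73 CPM, a fold of 0.906 (95% interval 0.752 to 1.09). Il2ra, which encodes CD25, stood at 0.959 (0.808 to 1.14), the inhibitory receptor gene Ctla4 at 1.05 (0.802 to 1.38), and Ikzf2, which encodes the transcription factor Helios, at 0.859 (0.738 to 1.0003). Of the Treg signature, 21 of 25 members were measured, with a median log2 fold of -0.06 and a range from -0.67 to 0.23. None was 2-fold apart, 4 intervals lay below 1, 1 above and 16 included 1, and the median lay at percentile 23.9 of 10000 random lists matched on expression. Over genes with at least 5 CPM in a library the list lay at percentile 2.06. Its lowest member was Entpd1, which encodes the ectonucleotidase CD39, at 0.628 (0.554 to 0.712), chosen after its value was seen. Which cells its reads came from was not measured. Of the suppressive molecules, Tgfb1 stood at 1.02 (0.993 to 1.06) and Ebi3, a subunit of interleukin 35, at 0.895 (0.711 to 1.13), and the list's 12 measured members ran from -0.51 to 0.34 in log2 fold, with 2 intervals below 1 and 1 above, at percentile 13.9. Il10, Ifng, Il4 and Il17a were not analysed here.

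Gene lists fixed before the data were examined were set against random lists in the same way. Of 39 lists with at least 5 measured members, 5 lay among the highest 2.5% and 8 among the lowest 2.5%, where 1.95 would do so by chance in all. In the list of macrophage, monocyte and neutrophil markers the intervals of 17 members lay below 1 and those of 2 above, C1qc, C1qb and Msr1 were at least 2-fold lower, and 0 of 10000 random lists had a median as low. The members above 1 were S100a9 and S100a8, alarmins of neutrophils, at 1.29 (1.24 to 1.35) and 1.26 (1.201 to 1.33), and were chosen for naming after their values were seen. Retnlg, another neutrophil gene of this list and also named after its value was seen, had an interval below 1. The 17 intervals below 1 include those of all 15 macrophage and monocyte members. As many measured neutrophil members of the list therefore lay below 1 as above.

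A further 5 lists of lymphocyte and homing genes were lower by small amounts. The B and plasma cell markers had a median log2 fold of -0.13 at percentile 0.03, with 12 of 15 intervals below 1 and 1 above, the former including the B cell receptor component Cd79a at 0.926 (95% interval 0.910 to 0.942) and the B cell lectin Cd22 at 0.877 (0.860 to 0.895). The chemokine receptor and homing list lay at -0.14, percentile 0.02, with 12 of 20 intervals below 1 and 1 above, and the naive and resting T cell list at -0.10, percentile 0.21, with 14 of 20 below and 1 above. Both hold the egress receptor gene S1pr1 at 0.907 (0.885 to 0.930), which B cells also express. The list of follicular helper T cells lay at -0.24, percentile 0.14, with 7 of 9 intervals below 1 and 0 above. Its most abundant members, Cxcr5 at 0.875 (0.839 to 0.912) and the B cell coactivator Pou2af1 at 0.914 (0.878 to 0.951), are expressed by B cells too. The Th1 and cytotoxic list lay at -0.17, percentile 0.67, with 9 of 15 intervals below 1 and 3 above and a highest member at a log2 fold of 0.44. Its most abundant members were Runx3 at 0.911 (0.858 to 0.968) and Ly6c2 at 0.932 (0.893 to 0.972). None of the members of these 5 lists was 2-fold apart. CD4 itself, Cd4, stood at 0.759 (0.650 to 0.886) with 394 and 292 reads, and Cd3e, a chain of the T cell receptor complex, at 0.952 (0.872 to 1.04).

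The effector Treg list had a median of -0.12 at percentile 1.49, with 6 of 17 intervals below 1 and 4 above, although its most abundant members were higher, Itgb1 at 1.03 (95% interval 1.01 to 1.05) and S100a6 at 1.19 (1.16 to 1.22), both expressed by many adherent cells. This list no longer lay among the lowest 2.5% with the mean in place of the median, at percentile 3.06, or over genes with at least 5 CPM in a library, at 8.23. The apoptosis regulators lay at -0.06, percentile 2.33, with 10 of 19 intervals below 1 and 5 above, and at percentile 17.9 with the mean. Their most abundant members were Mcl1, a survival factor, at 0.958 (0.941 to 0.976) and Xiap, a caspase inhibitor, at 0.898 (0.865 to 0.931).

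The 5 lists that stood apart as higher did so by small amounts. The cell cycle list had a median log2 fold of 0.16 at percentile 100 over 32 measured members, of which 26 had intervals above 1, such as the spindle factor Tpx2 at 1.03 (95% interval 1.01 to 1.05). Mki67, which encodes the proliferation antigen Ki-67, went the other way, at 0.880 (0.859 to 0.902), and was the only member with an interval below 1. The nuclear genes of oxidative phosphorylation lay at 0.14, percentile 100, with 22 of 26 intervals above 1, including the ATP synthase subunits Atp5a1 at 1.08 (1.06 to 1.10) and Atp5b at 1.09 (1.08 to 1.10). The p53 target list lay at 0.14, percentile 99.95, with 11 of 17 intervals above 1 and 2 below and a lowest member at a log2 fold of -0.14. Its most abundant members were Mdm2, the p53 ubiquitin ligase, at 1.11 (1.08 to 1.15) and the kinase gene Plk2 at 1.04 (1.01 to 1.07). The cholesterol synthesis list lay at 0.09, percentile 98.6, with 10 of 22 intervals above 1 and 0 below. Of its most abundant members, Srebf2, the sterol-responsive transcription factor, stood at 1.06 (1.03 to 1.09) and Hmgcs1 at 1.003 (0.951 to 1.06). All 40 ribosomal protein genes had intervals above 1, with a median of 0.12 at percentile 100, Rplp0 at 1.19 (1.18 to 1.199) and Rpl4 at 1.07 (1.06 to 1.08).

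Folds also went with transcript length across genes. Over the 13381 genes with a known transcript, Spearman's rho between length and log2 fold was -0.32, across genes, which are not independent replicates. The shortest 10% of genes had a median log2 fold of 0.09 and the longest 10% one of -0.11. The ribosomal protein transcripts were short, with a median of 1124 bases, and against random lists matched on length as well as expression this list lay at percentile 74.8 and the oxidative phosphorylation list at 96.0. The random lists could draw members of the list itself. With length matched, 8 lists came to lie beyond the limits of 2.5%. The matrix-producing cell markers stood higher, at percentile 99.94, and the others lower, namely T cell activation (1.47), type I interferon response (0.79), interferon gamma response (1.81), actin cytoskeleton (0.81), and the markers of dendritic cells (1.73), NK and innate lymphoid cells (1.71) and erythroid cells and platelets (0.32). With the trend on length and GC content removed, the ribosomal protein and oxidative phosphorylation lists stayed among the highest 2.5%, at percentiles 98.3 and 99.4. In that setting the p53 list lay at percentile 97.3 and the matrix-producing cell markers at 82.9, and 9 lists came to stand lower. Those not lower under length matching were T cell identity (0.85), the calpain system (1.39), and adhesion molecules and integrins (0.10). The macrophage list remained at percentile 0.00 in both settings, which were chosen after the data were seen.

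**Figure D2:**
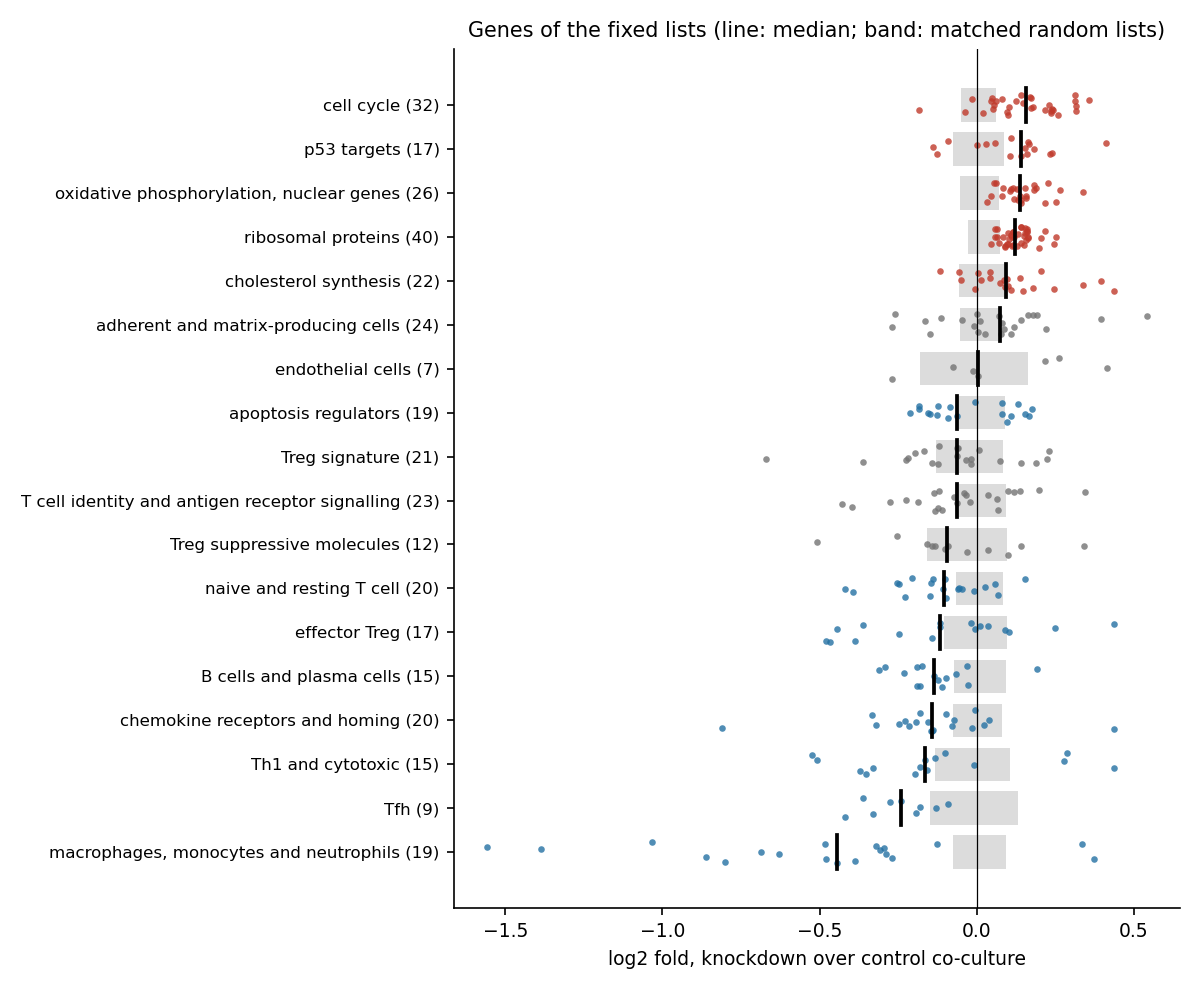
Each point is the log2 fold of 1 gene, knockdown over control co-culture (1 library per group), for the 13 fixed lists standing apart (red higher, blue lower) and 5 others of interest (grey), with measured members in brackets. Black lines are list medians and grey bands hold the central 95% of the medians of 10000 random lists, and the macrophage list's median of -0.44 lies farthest from its band.

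Markers of B cells, myeloid cells and matrix-producing cells had higher median levels than the Treg signature and the T cell identity list in both libraries. The median level of the B and plasma cell markers was 197 CPM in the control and 177 CPM in the knockdown co-culture library, against 5.89 and 5.65 CPM for the Treg signature and 22.3 and 22.6 CPM for the T cell identity list. The macrophage, monocyte and neutrophil markers had medians of 43.0 and 35.2 CPM and the matrix-producing cell markers 128 and 133 CPM. Not all lists followed this order, since the naive and resting T cell list, which holds genes that B cells share, had medians of 107 and 98.2 CPM and the T cell activation list 45.3 and 45.0 CPM. The erythroid and platelet markers (23.3 and 18.3 CPM) lay above the T cell identity list in the control and below it in the knockdown co-culture library, and the markers of CD8 T cells (7.58 and 8.85 CPM) and of NK and innate lymphoid cells (6.85 and 9.004 CPM) lay below it in both. Cd79a stood at 559 and 517 CPM, Lyz2, the lysozyme of myeloid cells, at 875 and 643 CPM, the beta globin gene Hbb-bs at 856 and 758 CPM, and the collagen gene Col5a2 at 1009 and 933 CPM. Cd3e stood at 22.3 and 21.2 CPM and Cd4 at 8.22 and 6.25 CPM, while Cd8a, the co-receptor of CD8 T cells, stood at 63.9 and 56.5 CPM. Lyz2, Hbb-bs, Col5a2 and Cd8a were chosen after their values were seen. Of the endothelial markers 7 of 26 were measured, with a median of 10.6 and 10.5 CPM and a median log2 fold of 0.00 at percentile 54.2, and Pecam1, the endothelial adhesion molecule CD31, stood at 83.9 and 79.7 CPM. Cdh5, another endothelial marker, was not analysed here. The matrix-producing cell markers had a median log2 fold of 0.07 at percentile 96.9, although their summed level was 5200 CPM in the control and 5104 CPM in the knockdown co-culture library.

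**Figure D3:**
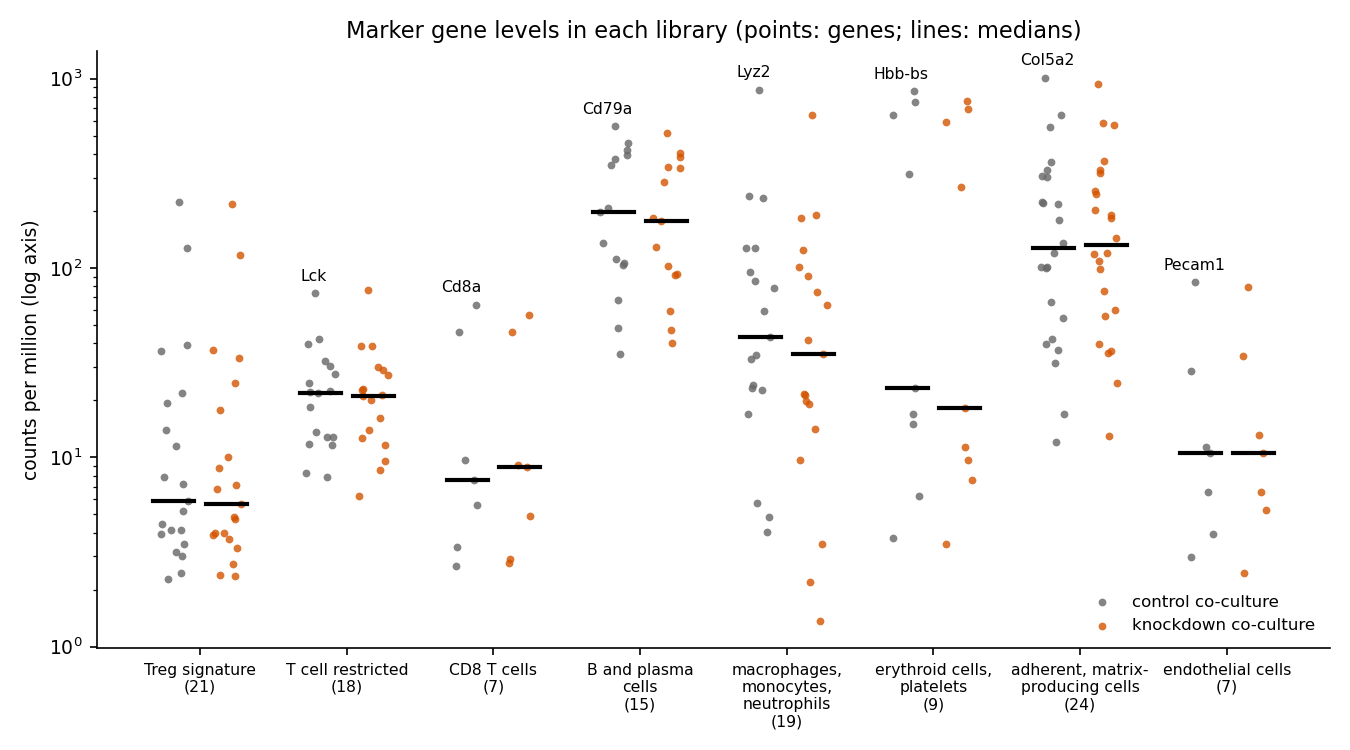
Each point is the level of 1 marker gene in CPM (log axis) in the control (grey) or the knockdown co-culture library (orange), by cell type, with the number of genes in brackets and black lines at the medians. The B and plasma cell medians of 197 and 177 CPM lie above those of the T cell restricted genes, 22.0 and 21.2 CPM, in both libraries.

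Against random lists matched on expression alone, the other fixed lists lay between the lowest and highest 2.5%. The T cell identity list lay at percentile 3.46, the markers of dendritic cells at 6.45, CD8 T cells at 17.2, NK and innate lymphoid cells at 4.19, and erythroid cells and platelets at 3.35. The lists of T cell activation and TGF-beta signalling lay at 6.65 and 2.95, those of Th2 and Th17 cells at 21.2 and 35.5, and interleukin 2 and STAT5 targets at 37.9. The type I interferon response lay at percentile 14.5 and the interferon gamma response at 12.5, with NF-kB targets at 37.6. Glycolysis lay at 92.4, the unfolded protein response at 91.0, heat shock at 85.3, hypoxia at 9.15, fatty acid metabolism at 15.5 and autophagy and lysosome genes at 41.4. Adhesion molecules and integrins lay at 2.58, actin cytoskeleton genes at 5.08 and the calpain system at 7.13. Too few members were measured to place the lists of mitochondrially encoded genes (0), replication-dependent histones (2), and gamma delta and conventional T cells (2). No gamma delta gene of the last list was measured.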

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

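The counts of 1 higher and 20 lower genes were the same under DESeq2 size factors, without ribosomal genes and with the deposited totals. They were also the same with an assumed coefficient of variation of 0.2, but this setting could not change any call. With at least 100 control reads and a 2-fold gap, every interval still excludes 1 there, so it says nothing of the spread between cultures. Total counts and upper-quartile scaling gave 22 lower genes, thinning 21, and removal of the length and GC trend 19, each with 1 higher gene. A fold threshold of 1.5 gave 43 higher and 180 lower genes, a threshold of 4 gave 0 and 0, and an interval wholly beyond 2-fold gave 0 and 7, by their construction. With at least 5 CPM in a library, 12 genes were lower, 10 of them shared with the 20, and with at least 400 reads in both libraries together 9 were lower, 8 of them shared, since fewer genes entered. The setting without a filter moved nothing, as all listed genes pass. The minimum of 400 reads, the deposited totals, the trend removal and the length-matched lists were chosen after the data were seen.

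The number of lists standing apart was 13, and 21 with the trend on length and GC content removed, and the cause was not tested. It lay from 13 to 19 in the other settings. Of 349 list percentiles under alternatives, 310 kept their side of the limits, 31 came to stand apart, 8 ceased to, and 0 turned. The adhesion and the erythroid lists came to stand apart as lower under 5 of 9 alternatives each, and the Treg signature under 2 (2.06 at 5 CPM, 1.98 at 400 reads), over its more abundant members. The 8 were effector Treg (8.23 at 5 CPM, 3.06 with the mean, 7.13 at 400 reads), apoptosis regulators (2.66 with 10 bins, 17.9 with the mean), p53 targets, oxidative phosphorylation and ribosomal proteins. Of 192 folds of named genes 190 stayed within their counting intervals and 2, Rpl4 and Rplp0, moved slightly beyond them under upper-quartile scaling. No paired analysis was possible because each group has 1 library. Depth limits the low genes most, and the interval of Foxp3 reached from 0.752 to 1.09. In simulation 60% of genes changed 2-fold were called. That share follows largely from a call threshold equal to the simulated fold, so it does not measure the effect of depth.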

Other observations

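The lists, genes and tests of this part were chosen after the data were seen. In a list of tissue macrophage genes, 10 of 20 measured members were at least 2-fold lower in the knockdown co-culture library, and the median log2 fold was -1.01. The list was written after macrophage genes had been seen among the lower genes, so these values describe it and do not test it. Spp1, which encodes osteopontin, had 69462 reads in the control and 38644 in the knockdown co-culture library, a fold of 0.570 (95% interval 0.563 to 0.577). Csf1r, the receptor for macrophage growth factor, stood at 0.551 (0.507 to 0.598) and Mmp12, macrophage elastase, at 0.502 (0.474 to 0.532). Of the 20 intervals 18 lay below 1, such as that of Gpnmb at 0.887 (0.870 to 0.904), 1 above, that of Axl at 1.08 (1.05 to 1.10), and 1 included 1, that of Apoe at 0.992 (0.970 to 1.01). The chemokine list had a median of -0.17, with 7 of 14 intervals below 1, 3 above and 4 including 1, and none of its members was 2-fold apart. Ccl7 and Ccl2, which attract monocytes, stood at 0.543 (0.514 to 0.573) and 0.665 (0.634 to 0.698), Ccl22, which attracts Tregs, at 1.59 (1.38 to 1.83) and the interferon-induced Cxcl10 at 1.501 (1.32 to 1.70).

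Most members of a list of neutrophil granule and precursor genes, also written after some had been seen, went the opposite way. Of 21 measured members 17 had intervals above 1 and 2, Retnlg and Mmp8, below, and the median log2 fold was 0.54. The primary granule genes Prtn3, Mpo and Elane stood at 1.96 (95% interval 1.796 to 2.15), 1.69 (1.62 to 1.76) and 1.67 (1.55 to 1.795), and the secondary granule genes Camp and Ltf at 1.94 (1.64 to 2.31) and 1.65 (1.53 to 1.78). None reached 2-fold. Retnlg, a gene of mature neutrophils, stood at 0.717 (0.583 to 0.879). The list of mast cell, basophil and eosinophil genes lay at percentile 63.5 and that of matrix metalloproteinases and inhibitors at 18.3, the latter with Mmp13 at 0.563 (0.515 to 0.614) beside Mmp12.

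The lower macrophage genes were weighed on the 15 macrophage and monocyte members of the fixed marker list, leaving out its neutrophil genes, with a median log2 fold of -0.48. After removal of the trend on transcript length and GC content the median was -0.52 (quartiles -0.84 to -0.35), and over the 13 members with at least 400 reads it was -0.44, so neither that trend nor the listing minimum accounts for it as a whole. A lower share of all spleen-derived cells alike would move B cell genes as far, and the median lay below that of the B cell markers by a log2 difference of -0.35 (95% interval from resampling members -0.69 to -0.14). The resampled genes are not independent replicates, and this interval holds no spread between cultures. A smaller number of macrophages beside the Tregs and lower expression per macrophage both stay open, since a bulk library cannot separate them. A response to the interfering RNA in the endothelial partner and a difference between single cultures or isolations are confounded, with 1 library per group, and either may lie behind the pattern.

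For the granule genes, removal of the length and GC trend left a median log2 fold of 0.42 (quartiles 0.34 to 0.69), against 0.54 before, so the trend accounts for at most part of it. A smaller macrophage share would raise the genes of all other cells alike, and library scaling removes most of a rise that is shared. The fixed B cell markers, with a median log2 fold of -0.13 and the highest at 0.19, are therefore no separate test of this. The values show only that the granule genes stood above the B cell markers, which a shared rise alone would not give. A larger share of immature neutrophils, which make granule transcripts, is a candidate explanation and stays untested by any independent measure, as does a difference between cultures. The measured neutrophil members of the fixed marker list went both ways.

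The third pattern is the makeup of both libraries, labelled as CD4+CD25+ Tregs. Of 18 genes largely restricted to T cells within the T cell identity list, 0 lay above the median of the B cell markers in either library, and the highest, Lck, stood at 73.4 CPM in the control, so the pattern does not rest on poor counting of a few T cell genes. The B cell median was 8.97 times that of the T cell genes in the control and 8.36 times in the knockdown co-culture library. Of the 15 measured B cell markers 0 and of the 15 macrophage and monocyte markers 1, Itgam, are also in another fixed list. Cells of another type bring all their abundant transcripts, and of 12 further B cell genes outside the fixed lists 10 lay above the T cell median in both libraries, with Fcmr at 324 and 320 CPM and H2-Ob at 227 and 194 CPM. These B cell levels argue against libraries of CD4+CD25+ T cells alone, for the genes listed here. RNA of other cells in both libraries is a candidate explanation that this test did not exclude, and its source was not measured. Isolation on CD4 and CD25 would remove most B cells and myeloid cells, which the marker levels do not show. Reads of Cd79a were 25.04 and 24.4 times those of Cd3e, those of Lyz2 39.2 and 30.3 times and those of the collagen gene Col1a1 24.8 and 27.4 times. Cd8a had 7.77 and 9.05 times the reads of Cd4. Which cells carried the differences between these libraries was not measured.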
